A study of Mus musculus with 39 samples.

How the data were processed

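ChIP-seq with antibodies against GR or ER was performed on sonicated nuclei of 7438 mouse mammary cells and of 7438 cells with Afos, per the labels' protocols. Of the 39 samples, 24 had a list of called sites and were used: 8 from 7438, 1 for each receptor and treatment, and 16 from 7438 Afos, 2 for each. The other 15 samples, which are second replicates of 7438, input libraries and libraries of an ER with a mutated DNA-binding domain, were not analysed here. Mouse build mm9 and the software CASAVA 1.8 are named per the submitters' processing notes. The aligner, the peak caller, its control and its threshold are not given in the sources used here.

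Each deposited list holds 1 site a row. Per the file headers, a site carries its highest and its average tag density, a signal value of the authors, and a z-score, the score the authors gave each site. The 7438 Afos lists also carry a deposited p-value, which was not used in any result. How tag density was scaled is not stated, so it was ranked only within its own list; the exception is an alternative that applied the lower limits of the 7438 lists to 7438 Afos. The lists of the 2 cell lines were made differently. In 7438 every site was 150 bp wide, with a highest tag density of at least 10 and a z-score of at least 15. In 7438 Afos sites were at least 251 bp wide, with list medians between 335 and 602 bp and z-scores from 10.2 upward. List lengths were therefore not compared between cell lines by a test. The numbering of sites in the 7438 lists runs beyond their number (to 21254 in the list of 10149 ER sites with Dex), so sites had been removed before deposit. Coordinates are printed as the lists give them, since the files do not say whether the first base counts as 0 or 1.

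Groups were taken from the sample labels. For 7438, the names of the lists filed under untreated and Dex+E2 contradict the labels for both receptors. The labels were kept as the main reading, and exchanging these lists was fixed as an alternative. The comparisons of these lists are given in both readings.

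Sites were compared by overlap of at least 1 bp in the same chromosome. A reproducible site of 7438 Afos was made from overlapping sites of both replicate lists, merged. A reproducible site was kept if it overlapped at least 1 list of the other treatment, and lost or gained if it overlapped neither. Presence of the other receptor meant overlap with a reproducible site of that receptor. In 7438 the single lists took the place of reproducible sites. Shares carry exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only. Chance overlap was estimated from 100 random circular shifts of the sites along each chromosome. Site strength is the rank of the highest tag density within its own list, as a percentile.

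Gained and kept sites were compared with two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over 6 tests, and retention in 7438 Afos of ER sites with and without GR over 4. The ranks of sites with and without the other receptor were compared in 18 lists with a two-sided permutation test of 100000 resamples. Numbers of sites were compared by exact permutation, which with 2 lists a group cannot pass 0.05. The Fisher tests were checked on simulated lists with the 2383 reproducible ER Dex+E2 sites of 7438 Afos. A true odds ratio of 6 was recovered as 6.05 (4.81 to 7.66), and 14 of 200 draws without a difference fell below the 0.05 threshold. Simulated sites were independent and none was missed by a list, so clustered sites and calls that depend on site strength were not checked. The named sites are the 5 of highest rank in each class, as fixed before the data were examined; the text gives the leading ones.

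Alternatives fixed before the data were examined were a reciprocal overlap of at least 50%, sites at or above the median density of their list, equal numbers of sites from each list, leaving out each replicate, same-numbered lists as blocks, the exchanged 7438 lists, and retention only in both 7438 Afos lists. Added after the data were examined were the lower limits of the 7438 lists applied to 7438 Afos, removal of sites in untreated 7438 Afos lists, stratification by 5 classes of site strength, the centre of a 7438 site inside the Afos site, the rank comparison with the 7438 lists exchanged, and the further Fisher tests named as added in the results. Gene annotation and motif searches were left out, because no genome or gene positions in mm9 were used here. Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.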

Results

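Binding of the estrogen receptor (ER) and the glucocorticoid receptor (GR) to chromatin was mapped by ChIP-seq in 7438 mouse mammary cells, which carry tetracycline-regulated genes for GR fused to GFP and ER fused to Cherry. Both receptors are steroid-activated transcription factors. Cells were left untreated, or were given 100 nM dexamethasone (Dex, a synthetic ligand of GR), 100 nM estradiol (E2, the natural ligand of ER) or both hormones (Dex+E2) for 30 min. The same 4 treatments were given to 7438 cells carrying Afos. The labels do not explain that name, and A-Fos is known as a dominant-negative protein that keeps AP-1 factors off DNA. A list of called sites was used for 24 of the 39 samples. In 7438 Afos each receptor and treatment had 2 replicate lists, and in 7438 each had a single list. The lists held between 35 and 14160 sites. Sequencing depth is unknown, because the lists hold called sites and no read totals. The study asked how each receptor occupies the genome when the ligands are given alone or together.

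In 7438 Afos cells each receptor bound the genome widely only in the treatments that included its own ligand. GR lists held 205 ± 156 sites (mean ± SD, n = 2) in untreated cells, 7004.5 ± 2642 with Dex, 318 ± 243 with E2 and 12234.5 ± 2723 with Dex+E2. ER lists held 42 ± 9.90 sites in untreated cells, 51 ± 14.1 with Dex, 5366.5 ± 961 with E2 and 4234.5 ± 2362 with Dex+E2. The mean number of GR sites with Dex was 34.2 times that in untreated cells, and the ratio was 93.4 for replicate 1 and 16.3 for replicate 2. The mean number of ER sites with E2 was 128 times that in untreated cells, with 173 and 95.7 in the same-numbered replicates. With 2 lists a group, a two-sided exact permutation test cannot give a p below 0.333, which was the value for both contrasts.

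The added second ligand moved the number of sites less, and in different directions for the 2 receptors. GR had 1.75 times as many sites with Dex+E2 as with Dex, and both Dex+E2 lists were longer than both Dex lists (14160 and 10309 against 8873 and 5136). ER had 0.789 times as many sites with Dex+E2 as with E2, and the lists overlapped in length (5905 and 2564 against 6046 and 4687), so this difference lay within the spread between replicates. E2 alone left GR near its untreated number (ratio 1.55, with 5.16 and 0.463 in the same-numbered replicates). Dex alone left ER near its untreated number (ratio 1.21, with 1.74 and 0.837).

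**Figure D1:**
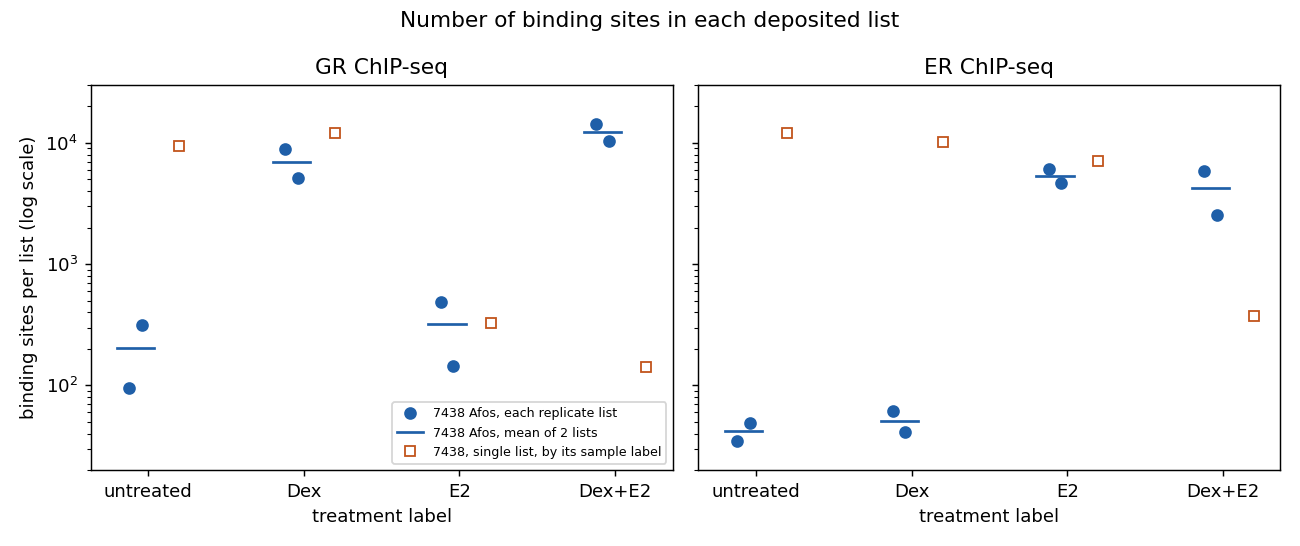
Number of binding sites in each list on a log axis, by receptor (panels) and treatment label. Filled points are the replicate lists of 7438 Afos and the lines their means, from 42 ER sites in untreated cells to 12234.5 GR sites with Dex+E2; open squares are the single 7438 lists, where the libraries labelled untreated hold 9503 GR and 11982 ER sites.

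Most sites of the shorter replicate list were found in the longer one for the ligand-bound receptors, while the longer list held further sites. The share of the shorter list found in the longer was 97.2% for GR with Dex, 88.5% for GR with Dex+E2, 91.5% for ER with E2 and 93.5% for ER with Dex+E2. It was 84.9% for GR with E2 and 70.5% for GR in untreated cells. For ER it was 37.1% in untreated cells and 41.5% with Dex, where lists were short. The share of the longer list found in the shorter was 56.0% for GR with Dex, 64.3% for GR with Dex+E2, 70.7% for ER with E2 and 40.4% for ER with Dex+E2. After random shifts along the chromosomes these shares averaged at most 0.686%. Sites found in both replicate lists are called reproducible below. There were 4961 for GR with Dex, 9084 for GR with Dex+E2, 4271 for ER with E2 and 2383 for ER with Dex+E2. Short lists left 65 and 122 for GR in untreated and E2-treated cells, and 12 and 17 for ER in untreated and Dex-treated cells.

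In 7438 Afos cells GR kept nearly all of its reproducible Dex sites when E2 was added, and further sites were called. Of the 4961 reproducible Dex sites, 99.5% were present in at least 1 Dex+E2 list (exact binomial 95% interval 99.3 to 99.7%), and 23 were absent from both. Of the 9084 reproducible Dex+E2 sites, 25.4% (24.5 to 26.3%), or 2304 sites, were in neither Dex list and are called gained. Gained GR sites were weaker than kept ones, with a median rank at percentile 44.6 of their lists against 65.0. When same-numbered lists were compared, the gained share was 44.8% in replicate 1 and 52.4% in replicate 2, above the share from reproducible sites. The kept share was then 88.1% and 96.1%. Between replicates of the same treatment, 56.0% of the longer Dex list and 64.3% of the longer Dex+E2 list were found in the shorter one. For the shorter lists the shares found in the longer were 97.2% and 88.5%. Whether gained sites had been under the threshold of the Dex lists was not tested.

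The strongest kept GR site lay on chromosome 17 (mm9, 28649296 to 28651246), with a highest tag density of 634 and 434 in the 2 Dex+E2 lists. The next lay on chromosome 12 (101032696 to 101034097; 653 and 418). All 5 of the strongest kept GR sites overlapped ER in both Dex+E2 lists and in no E2 list. The strongest gained GR sites were on chromosome 10 (79088217 to 79089349; 234 and 117) and on chromosome 6 (147073248 to 147074254; 298 and 110, and 66484651 to 66485534; 234 and 97.0). All 5 of the strongest gained GR sites overlapped ER in both Dex+E2 lists and in both E2 lists. The strongest lost GR site, on chromosome 17 (28551006 to 28551509), reached 25.6 and 19.3 with Dex.

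In 7438 Afos cells the ER sites with E2 and with Dex+E2 overlapped in part, and sites were classed as lost, kept or gained. Of the 4271 reproducible E2 sites, 69.0% (67.6 to 70.4%) were present in at least 1 Dex+E2 list, and 1325 were in neither. Of the 2383 reproducible Dex+E2 sites, 24.2% (22.5 to 26.0%), or 577 sites, were gained. Lost sites had a median rank at percentile 38.8, against 57.8 for all reproducible E2 sites. Gained sites stood at 54.2, against 67.8 for kept ones. Whether weak sites fell under the threshold of a list was not tested. Comparing same-numbered lists, 55.8% of E2 sites were kept in replicate 1 and 37.0% in replicate 2, where the Dex+E2 list was the shortest of the 4. The gained share in those comparisons was 42.8% and 32.3%. The number of sites lost and gained thus moved with the list used. Any 2 incomplete lists give both classes, so their presence in each replicate does not show a redistribution. Between replicates of the same treatment, 70.7% of the longer E2 list and 40.4% of the longer Dex+E2 list were found in the shorter one. For the shorter lists the shares found in the longer were 91.5% and 93.5%.

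The strongest kept ER site was the chromosome 6 region in which GR was gained (147073266 to 147074231), with a highest tag density of 369 and 124. The strongest gained ER site was the chromosome 17 region that held the strongest kept GR site (28649424 to 28650418; 96.3 and 33.9). Further gained ER sites lay on chromosome 5 (112309195 to 112309954; 72.3 and 34.5) and chromosome 9 (43655663 to 43656466; 75.4 and 32.1). Of the 5 strongest gained ER sites, all overlapped GR in both Dex+E2 lists, and 4 did so in both lists with Dex alone; the exception was on chromosome 11 (95547271 to 95548005). The strongest lost ER sites were on chromosome 15 (77713063 to 77713808; 52.2 and 43.4 with E2, and 99415948 to 99416734; 51.4 and 38.3) and chromosome 12 (17006741 to 17007535; 49.0 and 34.0). None of the 5 overlapped GR in both Dex+E2 lists.

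The ER sites gained with Dex+E2 in 7438 Afos were GR-bound more often than the ER sites that were kept. A reproducible GR Dex+E2 site was present at 533 of 577 gained ER sites (92.4%, interval 89.9 to 94.4%) and at 1186 of 1806 kept ones (65.7%, 63.4 to 67.9%). The odds ratio was 6.33 (95% interval 4.57 to 8.95; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.30e-41 over 6 tests). In the same-numbered comparisons the gained share was 84.1 ± 5.61% and the kept share 65.9 ± 2.52% (mean ± SD, n = 2). The odds ratio was then 3.54 in replicate 1 and 2.27 in replicate 2, both past the threshold. At the 1325 lost ER sites, GR was present at 3.77% (2.81 to 4.94%), and in the same-numbered comparisons at 5.12% and 9.20% of lost sites. Sites are not independent replicates, so these tests describe the lists, and their intervals cover counting error only.

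Many of these gained ER sites were already GR sites with Dex alone. GR Dex sites were present at 309 of 577 gained ER sites (53.6%) and at 238 of 1806 kept ER sites (13.2%), an odds ratio of 7.59 (6.10 to 9.45; Fisher's exact test, adjusted p = 2.77e-80). The same-numbered comparisons gave 43.4 ± 1.56% for gained and 11.6 ± 0.671% for kept sites, with odds ratios of 5.82 and 5.84.

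The reverse comparison gave the same direction. An ER Dex+E2 site was present at 1026 of 2304 gained GR sites (44.5%) and at 687 of 6780 kept GR sites (10.1%), an odds ratio of 7.12 (6.34 to 7.99; Fisher's exact test, adjusted p = 3.67e-258). Replicates differed in size: ER was at 48.2% of gained and 18.3% of kept GR sites in replicate 1 (odds ratio 4.15), and at 22.1% and 11.7% in replicate 2 (odds ratio 2.15). In a comparison added after the data were examined, ER sites of E2 alone were present at 40.3% of gained and 5.35% of kept GR sites, an odds ratio of 11.9 (10.4 to 13.7). The same-numbered shares were 31.5% and 5.46% in replicate 1, and 20.9% and 5.28% in replicate 2. Carry-over of ER-bound chromatin, which stays open below for the GR lists with E2 alone, was not tested for these gained GR sites. In the same added family, GR was present with Dex+E2 at 1243 of the 2946 ER E2 sites that were kept (42.2%) and at 50 of the 1325 that were lost, an odds ratio of 0.0538 for lost against kept sites (0.0393 to 0.0721; Fisher's exact test, adjusted p = 3.42e-175 over 6 tests). Lost ER sites ranked lower (median percentile 38.8 against 57.8 for all reproducible E2 sites), and this contrast was not computed within classes of site strength.

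**Figure D2:**
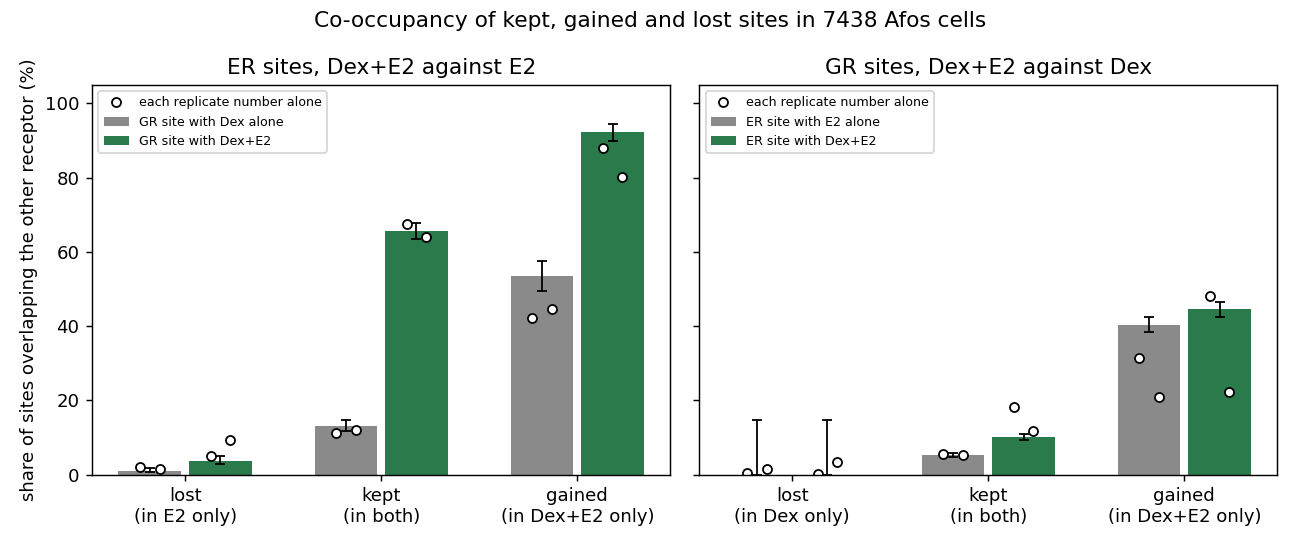
Share of lost, kept and gained sites (%) that overlapped the other receptor in 7438 Afos, for ER sites (left; Dex+E2 against E2) and GR sites (right; Dex+E2 against Dex). Bars are reproducible sites, with the other receptor taken from the single ligand (grey) or from Dex+E2 (green), error bars are exact binomial 95% intervals and circles are the replicate numbers taken alone; GR is at 92.4% of gained, 65.7% of kept and 3.77% of lost ER sites, and ER is at 44.5% of gained and 10.1% of kept GR sites, with 0 of the 23 lost GR sites (interval up to 14.8%).

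With both ligands most ER sites in 7438 Afos were shared with GR, while most GR sites were not shared with ER. GR was present at 72.1% (70.3 to 73.9%) of ER Dex+E2 sites, against 0.533% after random shifts, and ER was present at 18.9% (18.1 to 19.7%) of GR Dex+E2 sites, against 0.142%. In the same-numbered comparisons these shares were 72.8 ± 5.05% and 24.4 ± 10.3%. With E2 alone, GR was present at 460 of 6046 ER sites in replicate 1 and at 122 of 4687 in replicate 2. With Dex alone, ER was present at 10 of 8873 and 16 of 5136 GR sites.

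Shared sites ranked higher in their own lists than unshared ones. In Dex+E2 lists of 7438 Afos, ER sites with GR had a median rank at percentile 58.6 against 29.6 without GR in replicate 1, and at 58.5 against 32.8 in replicate 2. GR sites with ER stood at 66.4 against 42.8, and at 67.8 against 46.8. With E2 alone, the ER sites that carried GR stood 48.7 and 49.2 percentile points above those that did not. The difference was positive and past the threshold in 15 of the 18 lists tested, over both cell lines and all hormone treatments (two-sided permutation test on the difference of medians, Benjamini-Hochberg adjusted over 18). The test permuted single sites, which are not independent replicates. The GR and ER lists of a treatment were compared on the same shared regions, so the 18 lists are not separate evidence. For the Dex+E2 and E2 lists of 7438 Afos p was 1e-05 before adjustment, the smallest that 100000 resamples can give. In the Dex+E2 lists of 7438 shared sites stood 26.2 (GR) and 14.6 (ER) percentile points higher as labelled, and 20.5 and 29.8 with the lists exchanged, a rank comparison added after the data were examined. The difference did not pass for GR or ER with Dex in replicate 1 of 7438 Afos, each with 10 shared sites. In 1 list, GR with Dex in replicate 2, the 16 sites with ER ranked lower (percentile 12.9 against 50.2; permutation test, adjusted p = 0.000249).

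In 7438 cells the labels and the names of 4 lists were at odds, so those lists are named here by the label they were filed under. The libraries labelled untreated held 9503 GR and 11982 ER sites. Those labelled Dex+E2 held 143 GR and 373 ER sites. The Dex and E2 lists have no such conflict: GR had 12084 sites with Dex and 326 with E2, and ER had 7136 with E2 and 10149 with Dex. GR sites with Dex were 37.1 times as many as with E2, next to 22.0 times in 7438 Afos.

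By content, the lists labelled untreated held most of the sites that 7438 Afos cells occupied with Dex+E2. Of the 2383 reproducible ER Dex+E2 sites of 7438 Afos, 94.9% (93.9 to 95.7%) were in the ER list labelled untreated and 1.01% (0.646 to 1.49%) in the list labelled Dex+E2. Of the 9084 GR Dex+E2 sites, 64.9% and 0.892% were. The lists labelled untreated also held 83.4% of the reproducible ER E2 sites and 78.0% of the GR Dex sites of 7438 Afos. In the other direction, 84 of the 143 GR sites labelled Dex+E2 (58.7%) were in an untreated GR list of 7438 Afos, as were 2.28% of the 9503 sites labelled untreated. The same 143 sites were found more often in the Dex (74.1%) and Dex+E2 (77.6%) GR lists of 7438 Afos, which were far longer than the untreated ones. Of the 373 ER sites labelled Dex+E2, 1.34% were in an untreated and 12.1% in a Dex+E2 ER list of 7438 Afos.

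Taken as labelled, 1.12% (0.937 to 1.32%) of GR Dex sites in 7438 were kept with Dex+E2, and 9 of the 143 Dex+E2 sites were gained. ER kept 2.54% (2.18 to 2.93%) of its E2 sites, and 191 of 373 Dex+E2 sites (51.2%) were gained. GR was then less frequent at gained than at kept ER sites (7.33% against 22.5%; odds ratio 0.273, 0.132 to 0.535; Fisher's exact test, adjusted p = 4.14e-05). For GR from Dex alone the odds ratio was 0.197 (0.121 to 0.317; Fisher's exact test, adjusted p = 5.32e-13). For ER at gained GR sites it was 0.187 (0.00410 to 1.46), which did not pass (Fisher's exact test, adjusted p = 0.153). In the added comparisons, the odds ratio was 0.207 (0.0203 to 1.14) for ER from E2 alone at gained GR sites and 0.0187 (0.0114 to 0.0307) for GR at lost against kept ER sites. GR was present at 14.7% of ER Dex+E2 sites, and ER at 38.5% of GR Dex+E2 sites. If these lists had been exchanged, as their names have it, these values would not describe Dex+E2.

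With the untreated and Dex+E2 lists of 7438 exchanged, an alternative fixed before the data were examined, most of these values changed. GR kept 63.7% of its Dex sites and gained 18.9% of its Dex+E2 sites (1799 of 9503), while ER kept 88.3% of its E2 sites. ER gained 5684 of 11982 Dex+E2 sites (47.4%), a share within the interval of the labelled reading (46.0 to 56.4%). ER was present at 87.4% of gained and 37.6% of kept GR sites (odds ratio 11.5, 9.91 to 13.4). GR from Dex alone was present at 33.3% of gained and 17.8% of kept ER sites (odds ratio 2.31, 2.12 to 2.52). GR with both ligands was present at 38.9% and 35.9% (odds ratio 1.14, 1.06 to 1.23). GR was then present at 37.3% of ER Dex+E2 sites, and ER at 47.0% of GR Dex+E2 sites. The added comparisons gave odds ratios of 11.1 (9.91 to 12.5) for ER from E2 alone at gained GR sites and 0.185 (0.144 to 0.235) for GR at lost against kept ER sites. In this reading the strongest gained GR sites included the same 2 chromosome 6 regions as in 7438 Afos (147073683 to 147073833 and 66485006 to 66485156, with a highest tag density of 122 and 95.8). The chromosome 17 region was again among the 5 strongest gained ER sites (28649853 to 28650003; 134). As labelled, both chromosome 6 regions were instead among the 5 strongest lost ER sites (147073654 to 147073804 and 66485018 to 66485168; 291 and 299 with E2), and the chromosome 17 region was the strongest lost GR site (28649867 to 28650017; 759 with Dex).

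**Figure D3:**
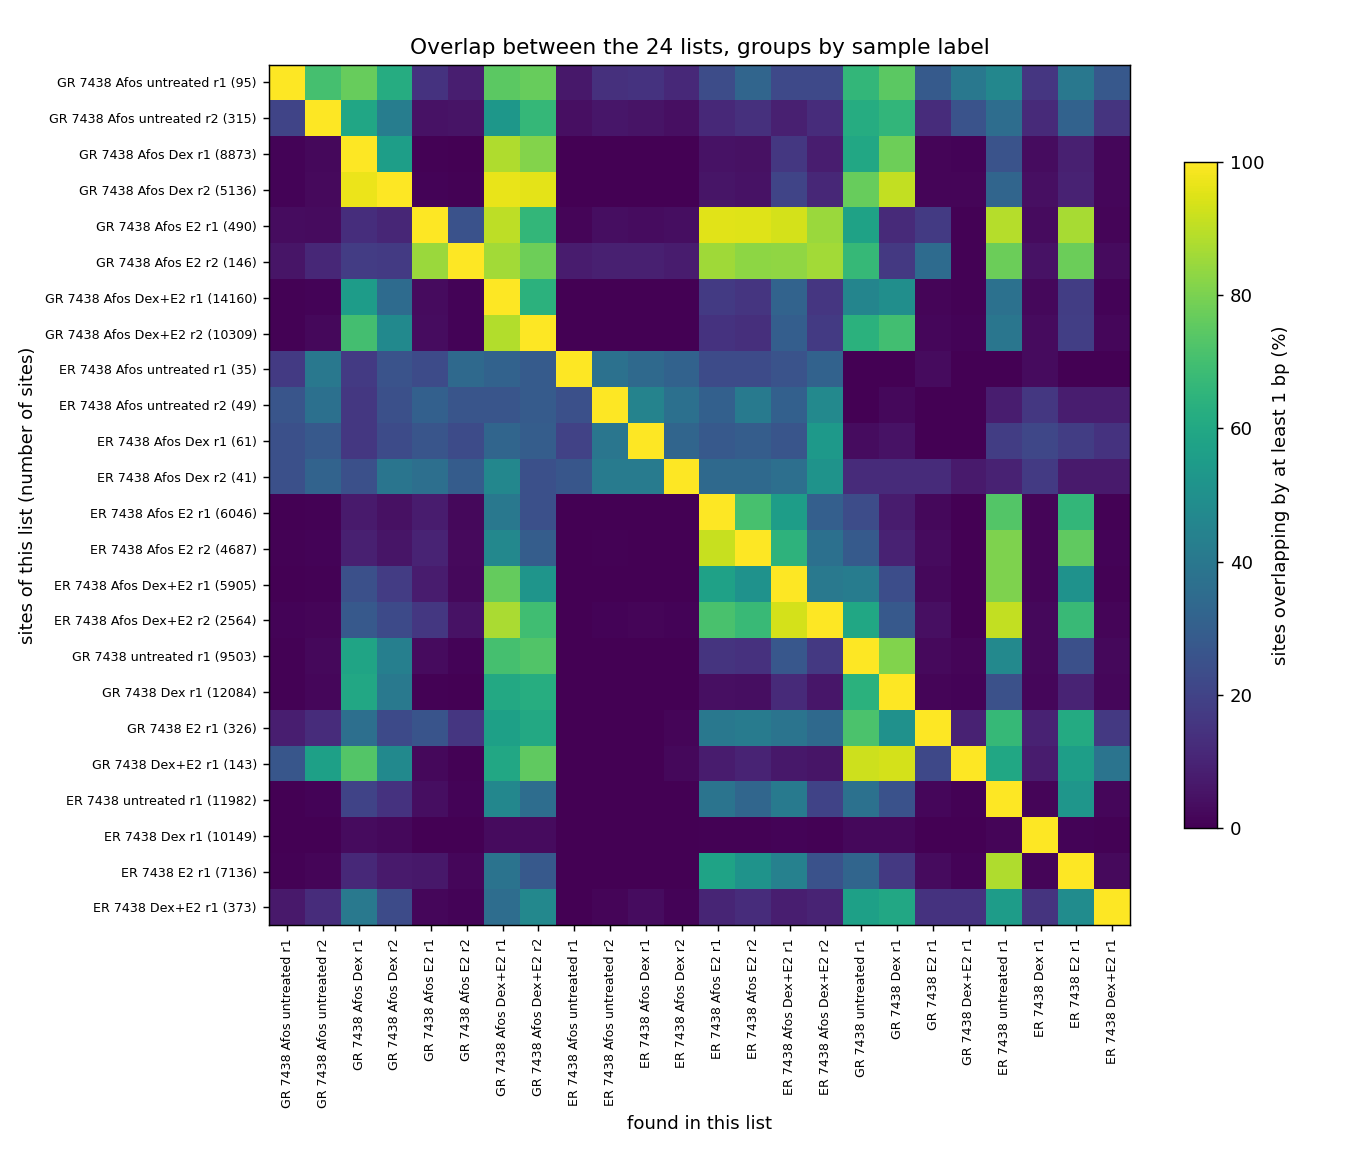
Share of the sites of each list (rows, with the number of sites) that overlapped each other list (columns) by at least 1 bp, in percent, for the 24 lists grouped by sample label; r1 and r2 are replicates. The ER Dex list of 7438 (10149 sites) is dark against every other list, and the GR E2 lists of 7438 Afos overlap the ER E2 and Dex+E2 lists rather than the GR Dex lists.

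The presence of Afos was compared by asking which 7438 sites were found in at least 1 list of the matching 7438 Afos group. This held for 60.5% (59.6 to 61.3%) of the 12084 GR Dex sites and for 60.5% (59.3 to 61.6%) of the 7136 ER E2 sites. Conversely, 92.1% of the 4961 reproducible GR Dex sites and 78.7% of the 4271 reproducible ER E2 sites of 7438 Afos were in the 7438 list. Strong sites were found more often: above the median density of their own list, 84.5% of GR Dex sites and 76.5% of ER E2 sites of 7438 were in 7438 Afos. Without Afos replicate 1 the GR Dex share was 40.3%. For Dex+E2 as labelled the shares were 77.6% of 143 GR sites and 12.1% of 373 ER sites, and with the lists exchanged 78.3% of 9503 and 41.8% of 11982.

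Among ER sites of 7438 with E2, 127 of 199 with GR (63.8%) and 60.4% of 6937 without GR were found in 7438 Afos, a difference that did not pass (odds ratio 1.16, 0.857 to 1.57; Fisher's exact test, adjusted p = 0.453 over 4 tests). It passed, with odds ratios of 1.58 to 1.98, in 4 alternatives with stricter lists or without replicate 1. The ER E2 sites with GR also ranked far higher (median percentile 93.3 against 49.2 without GR). Retention was not compared within classes of site strength, so it cannot be told apart from strength. With Dex+E2 as labelled, the values were 5 of 55 with GR and 40 of 318 without (odds ratio 0.696, 0.204 to 1.89; Fisher's exact test, adjusted p = 0.653). With Dex, where few ER sites were found in 7438 Afos at all, 4 of 235 with GR and 13 of 9914 without were (odds ratio 13.2, 3.11 to 43.1; Fisher's exact test, adjusted p = 0.00210). This call was lost without replicate 2 (odds ratio 7.08; Fisher's exact test, adjusted p = 0.162), with a reciprocal overlap of at least 50% and when presence in both 7438 Afos lists was required, both at 0 sites with GR. For the lists labelled untreated the values were 0 of 4470 with GR and 4 of 7512 without (Fisher's exact test, adjusted p = 0.453), and with the lists exchanged 0 of 55 and 5 of 318. With the Dex+E2 lists exchanged, ER sites with GR were found in 7438 Afos in 51.9% of cases and those without in 35.9% (odds ratio 1.93, 1.79 to 2.08). In that list too the sites with GR ranked higher (median percentile 70.4 against 40.6). No test was made between the cell lines, since 7438 had 1 list a treatment and the lists of the 2 lines were made with different site widths and lower limits.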

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

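Tests of the exchanged lists, of the labels being right, of ER binding with Dex alone that persists, of calls near background, of strongly enriched regions and of GR recruitment by E2 were chosen after the result was seen; those of amplified regions and of carry-over were fixed before.

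In 7 contrasts both 7438 Afos replicates moved one way and the 7438 lists, as labelled, the other way; none of these differences between the cell lines was tested. The ratio of GR sites was 0.0150 in 7438 and 59.7 in 7438 Afos for Dex+E2 over untreated, 0.0118 and 1.75 for Dex+E2 over Dex, and 0.439 and 38.5 for Dex+E2 over E2. The ratio of ER sites was 0.596 and 128 for E2 over untreated, 0.0311 and 101 for Dex+E2 over untreated, and 0.0368 and 83.0 for Dex+E2 over Dex. For Dex over E2, which involves no list whose label and name conflict, it was 1.42 and 0.00950. With the 7438 lists exchanged, the GR ratios become 66.5, 0.786 and 29.2 and the first 3 ER ratios 19.1, 32.1 and 1.18, in the same order.

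The first 6 contrasts share the lists filed under untreated and Dex+E2. If these had been exchanged when filed, the large lists would be expected to hold over 50% of the reproducible Dex+E2 sites of 7438 Afos. The ER list filed under untreated held 94.9% of them, and the GR list 64.9%. They also held 83.4% of the ER E2 sites and 78.0% of the GR Dex sites. With Dex+E2, 7438 Afos kept 69.0% of its ER E2 sites and 99.5% of its GR Dex sites. The shares of 83.4% and 78.0% alone therefore do not separate Dex+E2 from a single ligand. Against the single-ligand lists of 7438 the comparison is mixed. The E2 list held fewer of the ER Dex+E2 sites (71.4%), while the Dex list held more of the GR ones (69.2%). Of the 122 GR E2 sites, 77.9% were in the GR list filed under untreated, 18.9% in the Dex list and 41.0% in the E2 list. Of the 4961 GR Dex sites, the same lists held 78.0%, 92.1% and 1.49%. Of these lists, only the one filed under untreated held most of both sets, which neither single-ligand list did. The match to hormone-treated cells goes with an exchange, as do the names of the lists, but does not exclude right labels. The small lists speak less clearly. Of the GR and ER sites filed under Dex+E2, 58.7% and 1.34% were in an untreated list of 7438 Afos. In a Dex+E2 list were 77.6% and 12.1%, but those lists are much longer (for GR 14160 and 10309 sites against 95 and 315). In reverse, the GR list filed under Dex+E2 held 53.8% of the 65 reproducible untreated GR sites of 7438 Afos and 0.892% of the Dex+E2 ones. The long GR list filed under untreated held 75.4% of those 65 sites, and neither ER list held any of the 12 untreated ER sites. If the labels were right, both ligands together would have removed sites in cells without Afos. Untreated 7438 cells would also hold 9503 GR and 11982 ER sites, more ER sites than the 7136 with E2. Untreated lists of 7438 Afos, made with other limits, held 205 and 42 on average. The share of GR Dex sites in the list filed under Dex+E2, 1.12%, does not bear on such a removal, since a list of 143 sites could hold few of them in any case. For both receptors the content of the long list and the names of the lists argue against right labels. With a single list for each label, neither explanation is excluded.

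The contrast of Dex over E2 rests on the ER list of 7438 with Dex alone. Of its 10149 sites, 1.43% were in the ER list filed under untreated, which argues against ER binding with Dex that persists when E2 is added, if the lists were exchanged. As labelled, the Dex+E2 list held 0.562% of them, but with 373 sites it is too short to test this. A few amplified or repeated regions are argued against as well, since the 1% of 1 Mb bins with the most sites held 4.02% of them. Calls near the background level may make up most of the list, since 4.80% were in any of the other 23 lists, but this stays open because the share was also low, 16.8%, among the strongest 10% of its sites. ER binding seen with Dex alone and lost with any other treatment was not tested, since no replicate of this list was used.

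The GR lists of 7438 Afos with E2 alone are short but repeat, and 95.1% of their 122 reproducible sites lay at a reproducible ER E2 site. Strongly enriched regions entering the list of any antibody are argued against, but by the ER antibody only. Of the 102 sites in the ER Dex lists, 2.94% (0.611 to 8.36%) lay at the strongest 10% of GR Dex sites. The share of GR E2 sites at the strongest 10% of ER E2 sites was 57.7%. Those ER Dex lists repeated poorly (41.5% of the shorter was in the longer). Entry of such regions with the GR antibody alone was not tested. Carry-over of ER-bound chromatin in proportion to ER signal stays open: 62.1% of the strongest 10% of ER E2 sites were in a GR E2 list and 5.05% of the others, a ratio of 12.3. Recruitment of GR to ER sites by E2 may give the same picture, and the 95.1% cannot be told apart between them, as no library used here lacks either receptor.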

How the results depend on the processing

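The lower limits of the 7438 lists, the removal of untreated sites, the strength classes and the site centre were chosen after the data were examined. In 7438 Afos the odds ratios of the 3 comparisons of gained with kept sites stayed above 1 and past the threshold under every alternative run. Equal numbers of sites from each list were not run for these odds ratios. GR at gained ER sites ranged from 2.27 (without replicate 1) to 14.3 (strength classes), GR from Dex alone from 5.82 to 12.5, and ER at gained GR sites from 2.15 (without replicate 1) to 49.5. The cause of the changes below was not tested unless it is stated.

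Replicates share only a number, since the labels name no shared day. The list of replicate 1 was the longer in 6 of 8 groups. Compared as blocks of same-numbered lists, GR kept 92.1% of Dex sites and gained 48.6%, ER kept 46.4% of E2 sites and gained 37.5%, and the other 7 results stayed within their spread or past the threshold. Leaving out a replicate replaces reproducible sites by single lists. GR kept 88.1 to 96.1% of Dex sites and gained 44.8 to 52.4%, and ER kept 37.0 to 55.8% of E2 sites and gained 32.3 to 42.8%. ER was at 17.2 to 31.7% of GR Dex+E2 sites. The 7438 sites found in 7438 Afos were 40.3 to 59.8% (GR Dex), 60.1 to 75.5% (GR Dex+E2), 51.5 to 57.9% (ER E2) and 8.58 to 9.92% (ER Dex+E2), and the odds ratio for ER E2 sites with against without GR was 1.18 to 1.65, past the threshold without replicate 1 (Fisher's exact test, adjusted p = 0.00279).

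With equal numbers of sites from each list, GR in 7438 Afos kept 91.3% and gained 17.9%, and ER gained 32.9%. In 7438, where this cuts the longer list to 143 or 373 sites, GR kept 1.40% and gained 98.6%, and ER kept 3.75% and gained 96.2%, by construction. At or above the median of each list, GR was at 63.8% of ER Dex+E2 sites in 7438 Afos. In 7438, GR gained 12.5%, ER kept 1.76% and gained 66.3%, and the odds ratio of ER at gained GR sites was 0 and past the threshold (Fisher's exact test, adjusted p = 0.0218).

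With the 7438 lists exchanged, the ER ratio of Dex+E2 over E2 sites reversed to 1.68, and the odds ratios of GR at gained ER sites reversed to 1.14 and, for GR from Dex alone, 2.31. The odds ratio of ER at gained GR sites was 11.5 and that of ER retention with against without GR 1.93, both now past the threshold. GR kept 63.7% and gained 18.9% with a ratio of 0.786, ER kept 88.3%, GR was at 37.3% of ER sites and ER at 47.0% of GR sites, and 41.8% of ER sites were found in 7438 Afos.

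A reciprocal overlap of at least 50% left shares of 7438 sites in 7438 Afos of 2.30% (GR Dex), 2.10% (GR Dex+E2), 1.85% (ER E2) and 1.88% (ER Dex+E2), because a 150 bp site rarely covers 50% of a wider one; in 7438, ER kept 2.16% and gained 58.7%. With 7438 sites at or above their median, 84.5% (GR Dex) and 76.5% (ER E2) were found in 7438 Afos and the odds ratio of ER E2 sites with GR was 1.98. Required in both 7438 Afos lists, the shares were 39.6% (GR Dex), 58.0% (GR Dex+E2), 48.9% (ER E2) and 6.43% (ER Dex+E2), with an odds ratio of 1.68. Under the lower limits of the 7438 lists they were 49.4%, 69.2%, 50.3% and 8.58%, with 1.58. Those 3 odds ratios passed the threshold (Fisher's exact test, adjusted p = 0.0353, 0.00163 and 0.00770). All 11 results without untreated sites and all 12 with the site centre stayed as they were. The untreated lists held only 95 and 315 GR and 35 and 49 ER sites. Their removal could therefore move little and is a weak check.

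The number of lists in which shared sites ranked higher was 14 of 18 with the reciprocal overlap and 15 in the main comparison. Motif searches were not run, as no mm9 genome was used here. Read depth is unknown, so a site missing from a list may have been under the threshold.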

Other observations

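The tests of the regions, chromosomes and strength-matched values here were all chosen after the data were examined. Whether or not they reflect GR binding, the sites in the GR lists with E2 alone in 7438 Afos were mostly called with both ligands too. Of the 122 reproducible sites, 109 (89.3%) were GR sites and 115 (94.3%) were ER sites with Dex+E2, while 19 (15.6%) were GR sites with Dex alone and 12 (9.84%) were in an untreated GR list. The strongest lay on chromosome 6 (147073314 to 147074151; highest tag density 140 and 35.4, and 66484708 to 66485457; 70.5 and 25.9), which were among the 3 strongest gained GR sites with Dex+E2. Sites on chromosome 11 (79591888 to 79592647; 46.8 and 26.4) and chromosome 12 (113819958 to 113820837; 89.5 and 22.9) came next. In 7438 these GR sites were present at 41.0% with E2 and at 77.9% in the list labelled untreated, but at 0.820% (1 of 122) in the list labelled Dex+E2.

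In 7438 Afos gained sites were weaker than kept ones, so the association with the other receptor was also computed within 5 classes of site strength. The odds ratios then rose, to 14.3 for GR at gained ER sites, 12.5 for GR from Dex alone and 49.5 for ER at gained GR sites in 7438 Afos. In 7438 they were below 1 as labelled, at 0.279, 0.107 and 0.223, and above 1 with the lists exchanged, at 3.87, 3.72 and 31.0. In 7438 Afos the gained sites were thus shared more often in spite of their lower rank.

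Sites were unevenly spread over the chromosomes. Chromosome 11 held 8.39% and 8.68% of ER E2 sites in the 7438 Afos replicates and 9.53% in 7438, although it makes up 4.62% of the span covered by all lists. The X chromosome, 6.31% of that span, held 1.27% and 1.30% of ER E2 sites in 7438 Afos and 0.504% in 7438. In the untreated ER lists of 7438 Afos, X held 6 of 35 and 7 of 49 sites. No control library was used, so copy number was not examined.

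Merged over all 24 lists, the sites formed 37336 regions, of which 17652 were in a single list. Only 2 regions were in all 16 lists of 7438 Afos, on chromosome 3 (95848321 to 95849131) and the X chromosome (123302480 to 123303992), and neither was in any 7438 list. A region on chromosome 15 (74915812 to 74917170) was in 15 of them and in 2 lists of 7438.

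The share of ER Dex sites of 7438 that were in any other list rose with their density, from 2.07% in the weakest 10% to 16.8% in the strongest 10%. For ER E2 sites of 7438 the same shares were 80.4% and 100%, and 94.1% over all.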
